A study of Homo sapiens with 69 samples.

How the data were processed

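Gene expression was measured with TempO-Seq, a targeted assay in which paired probes are ligated on RNA in cell lysates, amplified and sequenced, with a human panel of 2982 transcripts, per the labels. The cells were an immortalised human renal proximal tubule line, as the parental line (Parent) or a line that overexpresses the organic anion transporter OAT1 (gene SLC22A6). They were cultured on platforms that the labels code CN and TW without spelling the codes out; the series title names static and fluidic culture. Cultures were untreated or exposed to cisplatin, tenofovir or PFOA from the apical or the basolateral side. Doses and exposure times are not given in the sources used here. The 69 samples formed 25 groups, of which 20 had 3 samples, 4 had 2 and 1 had 1. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

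The deposited values were a signal per gene: read counts divided by 1 size factor per sample. The submitters' processing notes name DESeq2, with no version. The aligner, genome build, read filter and any filter on genes are not given in the sources used here. The table held 2311 gene symbols, of which 2196 were found in the table of current gene names used here.

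In 68 of the 69 libraries the values were whole multiples of a single step, which gave back the reads. Over these libraries 100% of the values came out whole within a tolerance of 0.01 of a read. In the remaining library, CN Parent basolateral cisplatin replicate 1, the step lay too close to 1 for that check, so it stayed out of the count tests. Its smallest step gave 864276 reads, an unchecked number that was still used in read totals and in the correlation with read depth. Reads per library ranged from 269404 to 1754796, with a median of 983195. Medians were 917307 on CN and 1087851 on TW, 984035 in the Parent line and 963205 in the OAT1 line. Deposited totals ranged from 800119 to 1297854. The most abundant gene took at most 10.9% of a library, and the 10 most abundant took between 14.0% and 22.9%. In 6 libraries fewer than 500000 reads were recovered, and both CN Parent untreated libraries were among them. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Over 62 pairs of replicates the lowest chi-square per degree of freedom was 9.92, so none was treated as the same library deposited again.

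The groups, comparisons, gene lists, the rule for named genes and the alternatives listed at the outset were fixed before the data were examined. The design had allowed for recovered reads as an alternative, and limma on log2 values was kept as the main test. Genes with a mean deposited value of at least 10 over all samples were tested (1675 genes). Their log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 as a model with 1 mean per group over all 69 samples, with an intensity trend and 44 residual degrees of freedom. Fold changes are on this scale, which understates changes of low genes. P-values were adjusted by Benjamini-Hochberg within each comparison and called at 0.05. The 26 planned comparisons were joined by 10 chosen after results were seen: CN against TW in the OAT1 line and its difference from that in the Parent line, tenofovir on TW by side in the OAT1 line and basolaterally in the Parent line, tenofovir against PFOA on CN, and the differences of the tenofovir responses between platforms and lines.

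For each comparison, called genes with a mean of at least 50 in the higher arm were ranked by their change. Named genes were the 10 with the largest rise and the 10 with the largest fall. Up to 4 called members of each gene list with the smallest p, and SLC22A6, were named too. Y-linked genes, XIST and TSIX were not eligible to be named. The 19 gene lists covered proximal tubule transporters and markers, p53 and DNA damage, cell cycle, tubular injury, NRF2 and oxidative stress, the integrated stress and unfolded protein responses, PPAR and fatty acid oxidation, cholesterol and lipid synthesis, xenobiotic metabolism, mitochondrial respiration, NF-kB and cytokines, interferon response, mechanical stimulation and YAP targets, hypoxia and glycolysis, extracellular matrix, metallothioneins, heat shock and proteasome, cytoskeleton and junctions, and apoptosis. Each was tested with camera (limma) at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Of 494 list tests in the planned comparisons 78 were called, and 38 of these held with an estimated correlation. Lists of markers of other nephron segments, fibroblasts, endothelium and leukocytes had fewer than 5 tested members each and are given as values.

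Bimodal genes, 71 in all, had values at 2 separate levels within at least 3 groups, with a gap of at least 1.25 and at least 5 samples on each side. The median difference between their levels was 4.42 on the log2 scale, up to 8.85. Metallothionein (MT1) genes, UGT1A10, UGT1A8 and UGT1A6, histone genes and HSPA1A with HSPA1B have near-identical copies, and their values are uncertain where probes or reads could not be told apart.

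Alternatives were other pseudocounts (0.5 and 10), other filters (none, and a mean of at least 50), each sample rescaled to the same total, quantile normalization, only the groups of a comparison, sample weights, the replicate number as a block, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, and omission of each library in turn. Alternatives chosen after seeing the data were omission of bimodal genes, omission of libraries under 500000 reads, a library axis as a covariate, the 6 PFOA libraries as reference for tenofovir in the CN OAT1 line, and, for averages that include the single CN OAT1 untreated library, the average without the untreated groups. For CN against TW averaged over the Parent groups the count tests called 559 (edgeR) and 587 (DESeq2) genes, and limma called 575. The library axis was the first principal component of deviations from group means over the Parent libraries, on 1099 genes with a mean of at least 50 that were not bimodal. Every other library was scored on its loadings.

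The tests were checked on simulated data made from these samples, with 200 of 1675 genes changed. For CN against TW averaged over the Parent groups, limma recovered 180, with 15 false calls. By size this was 54 of 67 genes changed 1.5-fold, 61 of 67 changed 2-fold and 65 of 66 changed 4-fold. For untreated CN against TW in the Parent line it recovered 94, and 15.3% of its calls were false. For cisplatin in the Parent line it recovered 117 on CN, where 15.8% of calls were false, and 112 on TW, where 1.75% were. For basolateral tenofovir in the CN OAT1 line, against a single untreated library, it recovered 70. For the side of tenofovir dosing it recovered 158. The simulated values were drawn for each gene separately, so they lacked the variation that the library axis describes. The simulated shares of false calls may therefore be too low for the real samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.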

Results

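Gene expression was profiled in 69 samples of an immortalised human renal proximal tubule line. The Parent line contributed 20 libraries from the platform coded CN and 20 from the platform coded TW, and the OAT1 line contributed 10 from CN and 19 from TW. Groups held 3 libraries except the CN Parent untreated, TW OAT1 untreated, TW OAT1 basolateral tenofovir and TW Parent basolateral cisplatin groups, which held 2, and the CN OAT1 untreated group, which held 1. Reads per library ranged from 269404 to 1754796. CN libraries and TW libraries occupied separate parts of the assay plate, so platform could not be separated from plate position. Within each platform the lines also lay in separate wells, and each group lay in consecutive wells. Line, compound and side could therefore not be separated from plate position either.

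Within their groups, Parent libraries differed along a shared axis of expression that took 44.5% of the variance around the group means. It took 51% in TW Parent and 42.2% in CN Parent libraries when each was analysed alone, with loadings that correlated across genes at r = 0.887. Its high end held ZNF586 and ELAVL1, and its low end held MT2A, PRDX2, COX8A and GSTP1. The single CN OAT1 untreated library scored -17.5, and the other CN OAT1 libraries scored from -1.05 to 7.19. The TW Parent untreated libraries scored -17.6, 3.20 and 4.84.

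**Figure D1:**
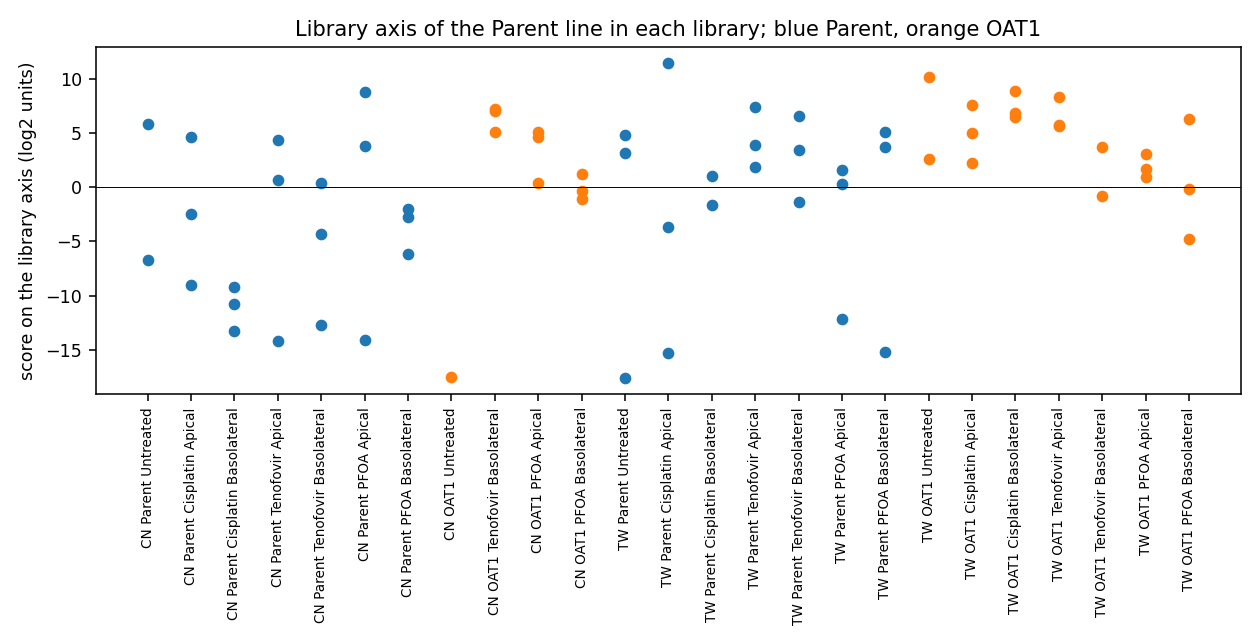
Score of each library on the axis of within-group variation of the Parent line, in log2 units, by group, with 1 point per library in blue for Parent and in orange for OAT1. The CN OAT1 untreated library lay at -17.5, and the other CN OAT1 libraries lay between -1.05 and 7.19.

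SLC22A6, which encodes OAT1, the transporter that takes organic anions up across the basolateral membrane, was examined first as a check of the line labels. Its deposited value lay between 331 and 1373 in every OAT1 library, with a mean of 600 ± 241 (SD, n = 29). In the Parent line it lay between 0 and 1.65, with 34 of 40 libraries at 0. The Parent libraries together held 8 SLC22A6 reads of 40382510, with a 95% Poisson interval of 3.45 to 15.8 reads. Within the OAT1 line the mean was 738 ± 352 (SD, n = 10) on CN and 527 ± 111 (SD, n = 19) on TW.

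**Figure D2:**
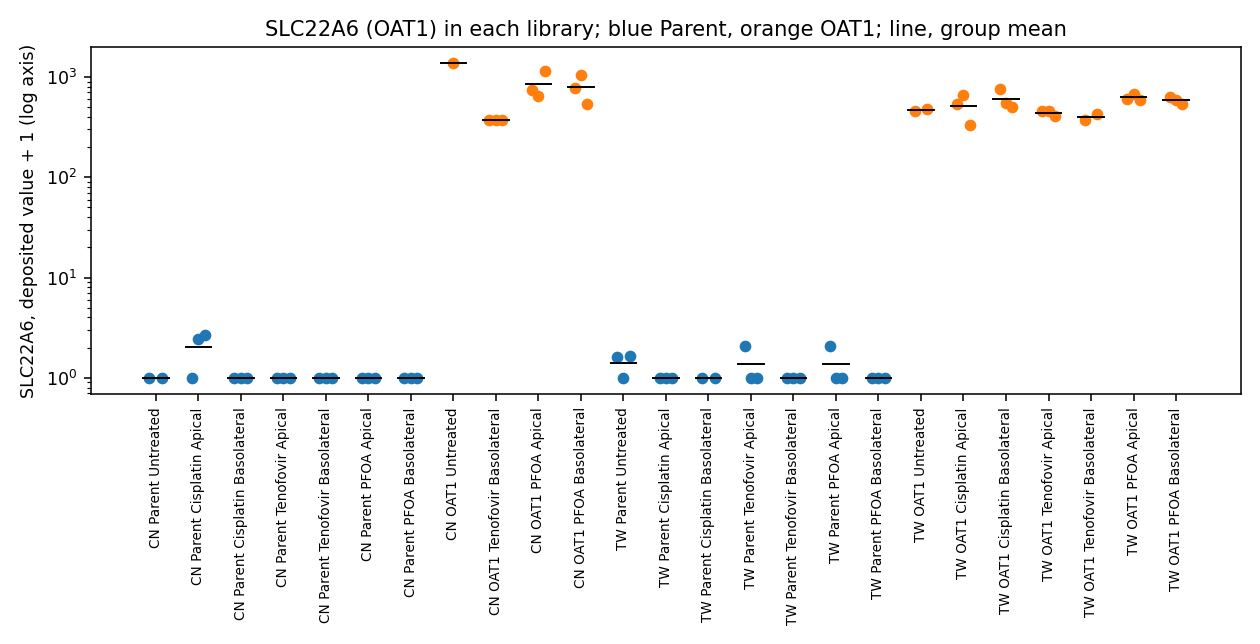
Deposited SLC22A6 value plus 1 on a log axis, with 1 point per library and a line at each group mean, for Parent groups in blue and OAT1 groups in orange. The OAT1 libraries lay between 331 and 1373, and the Parent libraries between 0 and 1.65.

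The series set the platforms against each other, and in the Parent line genes of the hypoxia response and glycolysis were lower on CN than on TW. NDRG1, a gene induced by low oxygen, averaged 97.3 ± 16.1 on CN and 1509 ± 537 on TW (SD, n = 20 each), a log2 change of -3.83 ± 0.12 (SE, limma adjusted p = 7.37e-30). All 20 CN libraries, at most 126, lay below all 20 TW libraries, at least 595. The glycolytic enzymes PGK1 (-2.12 ± 0.08) and ENO2 (-2.89 ± 0.12) and the vasoactive peptide gene ADM (-2.61 ± 0.21) fell too. Of 19 tested members of the hypoxia and glycolysis list 17 fell and 1 rose, or 18 and 1 adjusted over the list alone, with a median of -1.43 (camera adjusted p = 1.72e-23, and adjusted p = 3.04e-05 with an estimated correlation). The member that rose was HIF1A, the oxygen-regulated transcription factor subunit itself.

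Cell cycle genes were also lower on CN in the Parent line, where 21 of 36 members fell and 0 rose over all genes, and likewise adjusted over the list alone, with a median of -0.47 (adjusted p = 0.007 with an estimated correlation). The proliferation marker MKI67 fell by 1.49 ± 0.13, from 73.9 ± 23.9 on TW to 27.7 ± 13.4 on CN, and TYMS, which makes thymidylate for DNA synthesis, changed by -1.28 ± 0.11. NRF2 targets rose in 13 of 22 cases with 0 falling, on both counts, with a median of 0.37 (adjusted p = 0.0287 with an estimated correlation, 0.0503 with the library axis as a covariate), among them EPHX1 (1.12 ± 0.10) and ME1 (0.59 ± 0.08). Mitochondrial respiration genes rose in 10 of 18 cases and fell in 1, or 15 and 1 adjusted over the list alone, with a median of 0.29 (adjusted p = 0.0044 with an estimated correlation), and UQCRFS1, a subunit of complex III, rose by 0.61 ± 0.06. The extracellular matrix list, whose members are called matrix genes here, also covered epithelial-mesenchymal transition. Of its 19 genes 7 fell and 1 rose on both counts (median -0.16, adjusted p = 0.0287 with an estimated correlation). With the library axis as a covariate that adjusted p was 0.0503. VIM, the filament protein vimentin, led the falls (-1.92 ± 0.07). The calls for injury (2 rose and 8 fell), mechanical stimulation (2 and 9) and heat shock genes (5 and 0) were lost, with adjusted p = 0.071, 0.227 and 0.412 with an estimated correlation.

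Outside the lists, FKBP5, a glucocorticoid-induced co-chaperone, rose by 1.68 ± 0.10 (limma adjusted p = 2.34e-19) and averaged 305 ± 40.8 on CN and 95 ± 25.5 on TW (SD, n = 20 each), and CXCR4, a chemokine receptor, fell by 4.38 ± 0.24. MAOA, which degrades monoamines, rose by 1.14 ± 0.21. HAVCR1, the tubular injury marker KIM-1, fell by 1.42 ± 0.25. Proximal tubule markers were not called as a list (2 of 12 rose, 1 fell, camera adjusted p = 0.393). The stress response (8 rose and 5 fell of 23), PPAR (9 and 1 of 18), xenobiotic (7 and 2 of 16), cytoskeleton (3 and 6) and apoptosis lists (3 and 1 of 23) were not called either, with camera adjusted p = 0.141, 0.0633, 0.128, 0.341 and 0.341. Of markers of other nephron segments, KRT19 changed by -0.76 (adjusted p = 0.0143), and KRT7, a bimodal gene (-0.42), and MUC1 (-0.12) did not pass; the fibroblast markers COL1A1 (0.15), ACTA2 (-0.05) and TAGLN (0.01) did not pass, and no endothelial marker was tested.

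**Figure D3:**
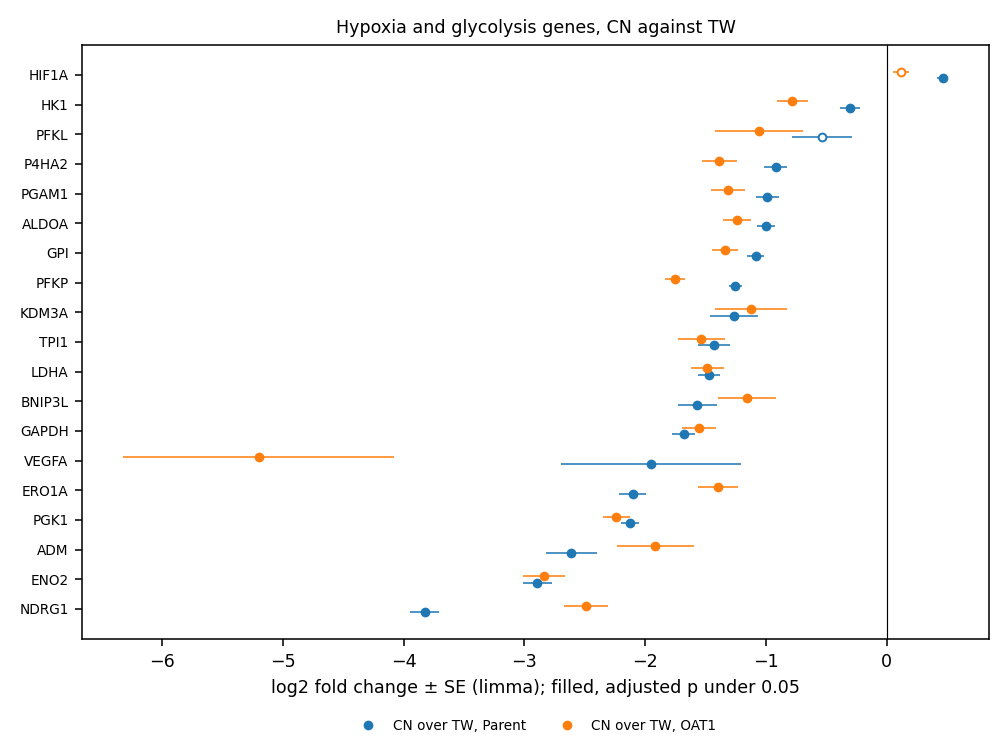
Log2 fold change of CN over TW with its standard error for the 19 tested hypoxia and glycolysis genes, in the Parent line (blue) and the OAT1 line (orange); filled points passed an adjusted p of 0.05. Most points lie below 0 in both lines, with medians of -1.43 and -1.40.

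Averaged over the 7 Parent groups, 575 of 1675 genes differed between platforms (277 higher and 298 lower on CN; 48.2% higher, or 62.3% when samples were rescaled to the same total and 54.7% with quantile normalization). With untreated cultures alone (2 CN against 3 TW libraries) 137 genes were called (41 higher and 96 lower, 29.9% higher, or 44% rescaled and 35.3% quantile). In these, hypoxia genes fell in 13 of 19 cases and rose in 1 (median -1.54, adjusted p = 1.39e-04 with an estimated correlation), with NDRG1 at -3.83 ± 0.35. Cell cycle genes fell in 8 cases (14 adjusted over the list alone, adjusted p = 0.0296 with an estimated correlation). The untreated count was 63 without CN Parent untreated replicate 2 and 87 without TW Parent untreated replicate 3, and only 19 with just the 5 libraries in the fit.

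The same platform comparison in the OAT1 line was added after results were seen. Over the 4 groups present on both platforms, 444 genes were called (213 higher and 231 lower on CN, 48.0% higher, or 37.6% rescaled and 56.5% quantile). Hypoxia and glycolysis genes fell in 18 of 19 cases (median -1.40, adjusted p = 2.74e-05 with an estimated correlation), with NDRG1 at -2.49 ± 0.18. Cholesterol and lipid synthesis genes rose in 12 of 13 cases (median 0.72, adjusted p = 0.00161 with an estimated correlation). Among them IDI1 of the mevalonate pathway rose by 1.08 ± 0.09, with 3274 ± 964 on CN and 1579 ± 119 on TW (SD, n = 10 each), and FASN, the fatty acid synthase (1.06 ± 0.11). Interferon response genes fell in 10 of 19 cases and rose in 1, or 11 and 1 adjusted over the list alone (median -0.48, adjusted p = 0.00744 with an estimated correlation), with IFI27 at -4.07 ± 0.35 and IFI6 at -1.77 ± 0.15. Metallothionein and metal response genes fell in 6 of 7 cases (median -0.98, adjusted p = 0.00161 with an estimated correlation), and matrix genes in 6 of 19, or 9 adjusted over the list alone (median -0.40, adjusted p = 0.00161 with an estimated correlation). Without the untreated groups the medians were 0.55 for cholesterol, -0.65 for interferon, -1.49 for metallothionein and -0.33 for matrix genes. NRF2 targets rose in 11 cases, or 14 adjusted over the list alone (adjusted p = 0.0216 with an estimated correlation, 0.0623 without the untreated groups), and calls for mechanical, NF-kB and heat shock genes were lost (adjusted p = 0.0923, 0.121 and 0.275 with an estimated correlation). SLC22A6 differed by 0.55 ± 0.16 (limma adjusted p = 0.00925), a call that was lost with a pseudocount of 0.5 and when the average left out the untreated groups, and with them the single CN OAT1 untreated library (0.22 ± 0.17, adjusted p = 0.371). The count of 444 was 417 there.

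The platform effect differed between lines for 144 genes by the test of the interaction (56 higher and 88 lower in the OAT1 line, 38.9% higher, or 43.3% quantile and 20.3% rescaled, where the median of all genes moved by -0.14). The count was 251 with the library axis as a covariate and 219 with sample weights. Cholesterol genes differed upward in 12 of 13 cases (median 0.88, adjusted p = 1.09e-04 with an estimated correlation). Interferon genes differed downward in 8 of 19 cases and upward in 1, or 11 and 2 adjusted over the list alone (median -0.63, adjusted p = 9.97e-04 with an estimated correlation). Metallothionein genes differed downward in 3 of 7 cases, or 4 (median -0.72, adjusted p = 0.00608 with an estimated correlation). Across genes, which are not independent replicates, the platform fold changes of the 2 lines correlated at r = 0.446, and 233 genes were called in the same direction, 20 in opposite directions, against 76.3 for independent lists. The CN side of the OAT1 comparison holds a single untreated library, which stood apart from the other CN OAT1 libraries on an axis of library variation. Without the untreated groups 135 genes differed between the lines, 83 of them among the 144, with list medians of 0.49, -0.82 and -1.27 (adjusted p = 0.00246, 6.2e-04 and 0.00105 with an estimated correlation).

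The OAT1 line was compared with the Parent line on each platform, and many genes besides SLC22A6 separated the lines. On TW, SLC10A2, a bile acid transporter, averaged 522 ± 143 in the OAT1 line (SD, n = 19) and 1.37 ± 1.26 in the Parent line (SD, n = 20). SLCO1B1, another organic anion transporter, averaged 236 ± 87.6 and 0.153 ± 0.386. In the other direction ESRP1, an epithelial splicing factor, averaged 0.576 ± 0.709 in the OAT1 line and 836 ± 271 in the Parent line, and MAOA 1.45 ± 1.59 and 204 ± 51.5. The fitted log2 changes of such genes, 8.82 ± 0.11 for SLC22A6, 7.98 ± 0.18 for SLC10A2 and -9.10 ± 0.18 for ESRP1 (limma adjusted p = 8.95e-41), depend on the pseudocount and are no bounds. ABCB1, the drug efflux pump P-glycoprotein, fell by 2.64 ± 0.09 on TW and by 3.16 ± 0.13 on CN.

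Mitochondrial respiration genes were lower in the OAT1 line on both platforms. On TW 14 of 18 fell and 1 rose (median -0.63, adjusted p = 0.00498 with an estimated correlation), and on CN 11 fell and 1 rose (median -0.68, adjusted p = 0.00625 with an estimated correlation). PPARGC1A, a coactivator of mitochondrial biogenesis, fell by 1.68 ± 0.05 on TW and by 2.87 ± 0.08 on CN, and SLC25A4, the ADP/ATP carrier, by 0.83 ± 0.06 and 0.91 ± 0.09. On TW, interferon response genes rose in 17 of 19 cases and fell in 1 (median 0.93, adjusted p = 0.0174 with an estimated correlation), with IFI6 up by 3.21 ± 0.10 and PSMB9, an immunoproteasome subunit, by 2.13 ± 0.09. In untreated TW cultures alone 7 interferon genes rose and 1 fell (adjusted p = 0.148 with an estimated correlation). Metallothionein genes rose on TW in 7 of 7 cases (median 1.11, adjusted p = 0.00498 with an estimated correlation). Cytoskeleton and junction genes fell in 10 of 14 cases and rose in 1, or 11 and 1 adjusted over the list alone (median -0.49, adjusted p = 0.018 with an estimated correlation). On CN the interferon list was not called (7 rose and 6 fell, median 0.20, camera adjusted p = 0.646), nor was the metallothionein list (3 rose and 0 fell, median 0.42, camera adjusted p = 0.269). These medians were -0.04 and 0.08 without the untreated groups. Also on CN, calls for cell cycle (24 rose and 4 fell, adjusted p = 0.0893 with an estimated correlation), cholesterol (9 and 0, or 13 and 0 adjusted over the list alone, 0.0893) and cytoskeleton genes (1 and 9, 0.0686) were lost. CXCL8, the chemokine interleukin 8, was higher in the OAT1 line by 3.81 ± 0.14 on TW and 2.08 ± 0.21 on CN.

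Markers of other cell types moved with the line, not all in the same direction. Of fibroblast markers, COL1A1 (1.29) and TAGLN (1.12) rose and ACTA2 fell by 1.10 on TW, and on CN the values were 1.18, 0.85 and -0.69. The antigen presentation gene HLA-DRA of the leukocyte list rose by 3.39 on TW and 4.29 on CN. Of markers of other nephron segments on TW, the bimodal gene KRT7 changed by -1.54 (adjusted p = 8.43e-04), KRT19 by 0.83 (adjusted p = 0.00454) and MUC1, which did not pass, by -0.04, and on CN KRT19 changed by 1.48 (adjusted p = 7.03e-04).

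In all, 948 genes differed between the lines on TW (488 higher and 460 lower in the OAT1 line; 51.5% higher, or 54.8% rescaled and 43.8% quantile). On CN 757 differed over the groups present in both lines (404 higher and 353 lower; 53.4% higher, or 48.1% rescaled and 49.1% quantile), and 824 without the untreated groups. Across genes the fold changes of the 2 platforms correlated at r = 0.866, with 576 genes called in the same direction and 19 in opposite directions, against 215 for independent lists. Untreated TW cultures alone gave 336 genes (183 higher and 153 lower; 54.5% higher, or 52.8% rescaled and 47.4% quantile), 182 without TW OAT1 untreated replicate 3 and 163 with only the 5 libraries in the fit. There mitochondrial genes fell in 8 cases and rose in 1 (adjusted p = 0.0189 with an estimated correlation), and metallothionein genes rose in 4 of 7, or 5 adjusted over the list alone (adjusted p = 0.0167). Calls for cytoskeleton and cholesterol genes were lost (adjusted p = 0.0531 and 0.539). The labels do not say how the OAT1 line was derived.

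Cisplatin, a DNA-damaging drug with toxicity to proximal tubule cells, raised p53 and DNA damage genes as a group in the Parent line on both platforms. BAX, the pro-apoptotic p53 target, averaged 1356 ± 116 in cisplatin (SD, n = 5) and 824 ± 102 in untreated TW cultures (SD, n = 3), a rise of 0.72 ± 0.10 (limma adjusted p = 9.39e-06), with every treated library above every untreated one. On CN it averaged 1607 ± 124 (SD, n = 6) against 1094 ± 331 (SD, n = 2), a rise of 0.58 ± 0.12 (limma adjusted p = 0.00326). On TW 1 of 24 p53 genes rose, or 3 adjusted over the list alone, with a list median of 0.62 (camera adjusted p = 1.01e-14, and adjusted p = 1.17e-08 with an estimated correlation). On CN 2 rose, or 6 adjusted over the list alone (median 0.49, adjusted p = 3.03e-04 with an estimated correlation). The other genes called on TW were UGT1A10, a glucuronidation enzyme with near-identical copies (1.70 ± 0.19), TRIM22 (0.89 ± 0.16), which was lost without TW Parent untreated replicate 3, and SAT1, which breaks down polyamines and fell by 2.42 ± 0.37. PFOA called SAT1 lower too, against the same untreated libraries.

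Other lists moved less. On TW the NRF2 list was called upward (0 members rose, 2 adjusted over the list alone, median 0.21, adjusted p = 0.0106 with an estimated correlation), as was apoptosis (1 member, BAX, median 0.11, adjusted p = 0.0275). Injury (median -0.23, adjusted p = 0.0261) and NF-kB genes (median -0.40, adjusted p = 0.0463, or 0.0743 with the library axis as a covariate) were called downward with 0 members past the threshold. Calls for cholesterol and hypoxia genes were lost (adjusted p = 0.051 and 0.0733 with an estimated correlation). On CN, calls for cell cycle genes (1 rose, 6 adjusted over the list alone) and mechanical genes were lost (adjusted p = 0.39 and 0.325 with an estimated correlation).

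Cisplatin called 4 genes on TW (3 higher and 1 lower; 48 at an unadjusted p under 0.05), 66 with sample weights and 1 with only the 8 libraries of the comparison in the fit. It called 22 on CN (17 higher and 5 lower), 8 without CN Parent untreated replicate 2 and 35 without replicate 3, and UGT1A10 rose there by 1.05 ± 0.21, a call lost without replicate 2, as the BAX call was without replicate 3. The 2 genes called on both platforms were BAX and UGT1A10, named after their values were seen, and across genes the fold changes correlated at r = -0.00358. The platforms' responses to cisplatin differed for 4 genes (4 higher on CN), but for 0 with quantile normalization, with edgeR or without TW Parent untreated replicate 1 and for 1 with only the groups of the comparison, and the p53 list was not called (median 0.04).

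In the OAT1 line on TW, cisplatin called 5 genes, of which CYP1B1, an aryl hydrocarbon receptor target, rose by 1.36 ± 0.29. The matrix genes MMP1 (-2.22 ± 0.50) and LAMA3 (-0.92 ± 0.18), the transporter SLCO2B1 (-1.95 ± 0.44) and AGR3 (-1.12 ± 0.23) fell. LAMA3 averaged 497 ± 99.5 in cisplatin (SD, n = 6) and 929 ± 70.3 untreated (SD, n = 2; limma adjusted p = 0.00824). Matrix genes fell in 2 of 19 cases (median -0.18, adjusted p = 0.0155 with an estimated correlation). Calls for cell cycle, mechanical, NRF2, NF-kB, hypoxia, cholesterol and interferon genes were lost (adjusted p = 0.0811, 0.0811, 0.102, 0.102, 0.102, 0.199 and 0.199 with an estimated correlation); the NF-kB list had a median of -0.22 but a mean of 0.19. The p53 list responded differently in the 2 lines by the test of the interaction (median -0.59, adjusted p = 8.85e-05 with an estimated correlation), in the direction of a smaller rise in the OAT1 line, and cholesterol genes differed upward (median 0.36, adjusted p = 0.0306). The count of 5 was 0 without TW OAT1 untreated replicate 3, 3 without apical cisplatin replicate 1, 12 without apical replicate 3 and 8 without basolateral replicate 1. The series holds no CN OAT1 cisplatin libraries.

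**Figure D4:**
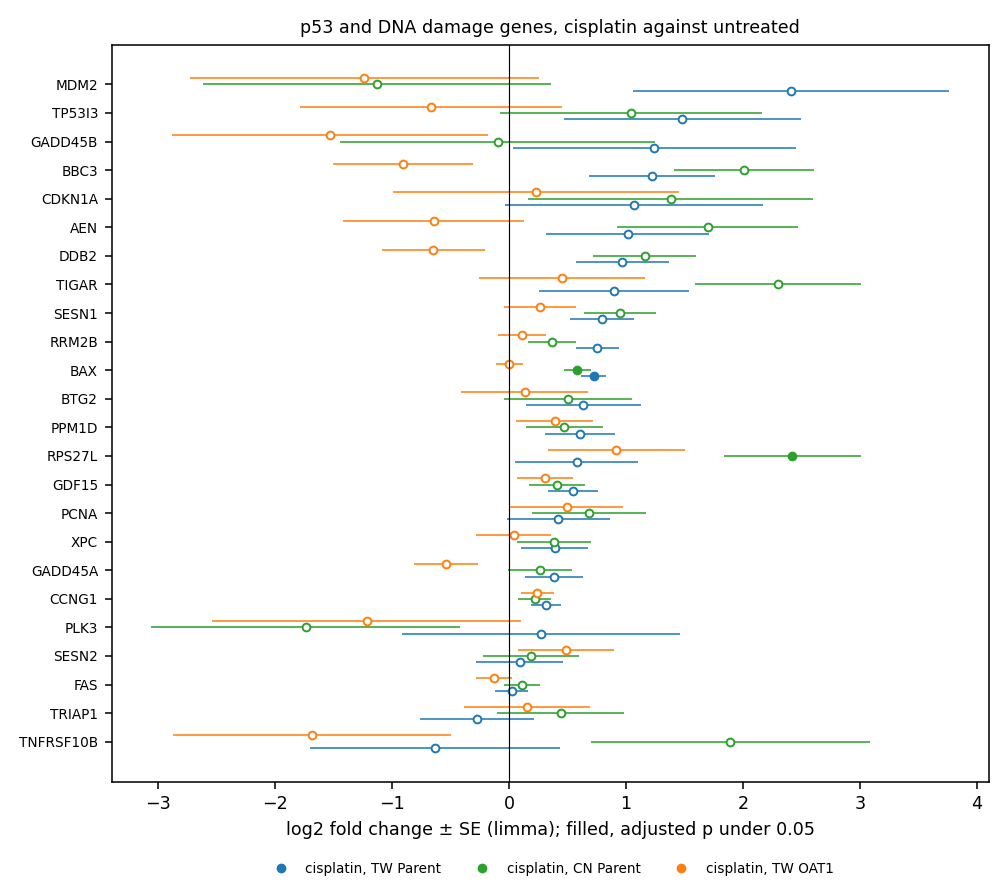
Log2 fold change of cisplatin over untreated with its standard error for the 24 tested p53 and DNA damage genes, in TW Parent (blue), CN Parent (green) and TW OAT1 cultures (orange); filled points passed an adjusted p of 0.05. The list medians were 0.62, 0.49 and 0.07.

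Tenofovir, an antiviral nucleotide that OAT1 carries into proximal tubule cells, gave its called responses mainly in the OAT1 line. On TW, interferon response genes rose in 9 of 19 cases, or 12 with 1 falling adjusted over the list alone (median 1.21, adjusted p = 6.66e-05 with an estimated correlation). IFI6 averaged 5137 ± 2911 in tenofovir (SD, n = 5) and 1199 ± 309 untreated (SD, n = 2), a rise of 1.76 ± 0.26 (limma adjusted p = 2.13e-05). IFIT1, an antiviral effector, rose by 1.88 ± 0.27 and HLA-DRA by 3.29 ± 0.53, and GDF15, a stress cytokine and p53 target, by 1.33 ± 0.24, a call lost without TW OAT1 untreated replicate 2. The p53 list rose in 1 case, or 4 adjusted over the list alone (median 0.31, adjusted p = 0.0185 with an estimated correlation). Metallothionein genes fell in 2 of 7 cases, or 4 with 1 rising adjusted over the list alone (median -0.51, adjusted p = 0.0181). The cell cycle list was called upward with 0 members past the threshold (median 0.44, adjusted p = 0.0201), and the NF-kB call was lost (adjusted p = 0.0765).

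The OAT1 responses on TW differed by side of dosing, a comparison added after results were seen. From the apical side interferon genes rose in 10 cases, or 13 with 1 falling adjusted over the list alone (median 1.65, adjusted p = 1.09e-06 with an estimated correlation). IFIT1 averaged 3551 ± 1091 (SD, n = 3) against 607 ± 200 untreated (SD, n = 2; 2.54 ± 0.29, limma adjusted p = 1e-08). NF-kB genes rose in 3 of 9 cases (median 0.84, adjusted p = 0.00803), and the hypoxia call was lost (adjusted p = 0.317). From the basolateral side cell cycle genes rose in 7 of 36 cases, or 24 adjusted over the list alone (median 1.02, adjusted p = 5.44e-06 with an estimated correlation). ASF1B, a histone chaperone of replicating cells, averaged 494 ± 54 (SD, n = 2) against 97.8 ± 8.91 (SD, n = 2; 2.33 ± 0.38, limma adjusted p = 7.74e-05). Metallothionein genes fell there in 3 of 7 cases, or 4 (median -0.78, adjusted p = 2.03e-05), with MT1M, which has near-identical copies, at -1.82 ± 0.26. The p53 genes rose in 2, or 3 (median 0.44, adjusted p = 0.0113), and the interferon call was lost (1 rose, 4 adjusted over the list alone, adjusted p = 0.0822). Basolateral against apical dosing called 77 genes (49 higher and 28 lower). Cell cycle genes were higher in 19 of 36 cases, or 30 (median 1.19, adjusted p = 3.4e-07), with ASF1B at 2.65 ± 0.34 and MKI67 at 2.05 ± 0.38. Interferon genes were lower in 5, or 9 (median -0.87, adjusted p = 0.00715), IFI6 by -1.50 ± 0.29, metallothionein genes were lower in 4 of 7, or 6 (median -1.60, adjusted p = 8.77e-06), and the NF-kB call was lost (adjusted p = 0.0736).

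Both sides together called 20 genes on TW in the OAT1 line (16 higher and 4 lower), 7 without untreated replicate 2, 9 without untreated replicate 3, 13 without apical replicate 3 and 12 without basolateral replicate 1, and 13 with the replicate number as a block. Apical dosing called 33 (29 higher and 4 lower, 87.9% higher, or 75.0% with quantile normalization) and 13 without untreated replicate 2. Basolateral dosing called 26 (21 higher and 5 lower, 80.8% higher, or 67.6% with quantile normalization), 10 without untreated replicate 3, 8 without basolateral replicate 1, 3 without replicate 2 and 7 with only the groups of the comparison. The side comparison gave 174 with sample weights, 38 without basolateral replicate 1 and 18 without replicate 2. Rescaling to the same total moved the median of all genes by 0.12 in both the basolateral and the side comparison.

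In the Parent line on TW limma called 0 genes for tenofovir (35 at an unadjusted p under 0.05; edgeR 0, DESeq2 3, 6 with sample weights), and 0 for basolateral dosing alone (16; edgeR 0, DESeq2 0). The cholesterol list was called downward for basolateral dosing alone (median -0.31, adjusted p = 0.0334 with an estimated correlation), and its call over both sides was lost (adjusted p = 0.0915). The interaction of line and tenofovir on TW called 7 genes, all higher in the OAT1 line, and the interferon list (3 higher, or 11 and 1 lower adjusted over the list alone, median 1.26, adjusted p = 0.00115 with an estimated correlation). Calls for cell cycle and cholesterol genes were lost (adjusted p = 0.0898 and 0.108). The 7 genes became 14 with DESeq2 and 19 with sample weights, 3 without TW Parent untreated replicate 1, 1 without TW OAT1 untreated replicate 2 and 3 without its replicate 3. For basolateral dosing the interaction called 4 genes (1 higher and 3 lower; 25% higher, or 66.7% rescaled, where the median moved by 0.19), 2 without TW OAT1 untreated replicate 3 or without basolateral tenofovir replicate 2. There the cell cycle list was higher in the OAT1 line (0 members over all genes, 13 adjusted over the list alone, median 1.07, adjusted p = 1.41e-04), and metallothionein genes were lower (1, or 4, median -0.75, adjusted p = 3.01e-04). Calls for p53, cholesterol and interferon genes were lost (adjusted p = 0.0961, 0.109 and 0.2).

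On CN, basolateral tenofovir in the OAT1 line went with higher expression of cell cycle genes and lower expression of metallothioneins. The only untreated CN OAT1 library stood apart on the axis of library variation, so the 3 tenofovir libraries were also set against the 6 PFOA libraries of that platform and line, a comparison chosen after results were seen. PFOA is itself a treatment, dosed here from both sides, so these differences may lie in either arm. TYMS averaged 4844 ± 237 in tenofovir (SD, n = 3) and 377 ± 46 in PFOA (SD, n = 6), a difference of 3.69 ± 0.24 (limma adjusted p = 1.24e-17). ASF1B averaged 1326 ± 94.1 and 62.3 ± 13.2, and the cell cycle repressor gene E2F8 differed by 3.99 ± 0.22. Of 36 cell cycle genes 31 were higher and 0 lower (median 2.28, adjusted p = 2.95e-08 with an estimated correlation). Of 24 p53 genes 14 were higher and 0 lower, or 15 and 1 adjusted over the list alone (median 1.42, adjusted p = 6.87e-05). GDF15 averaged 4654 ± 3012 against 986 ± 192, and BAX was higher by 0.69 ± 0.10 and BBC3, which encodes the death effector PUMA, by 3.45 ± 0.52. Of 7 metallothionein and metal response genes 6 were lower and 1 higher (median -1.53, adjusted p = 0.00172), with MT1M at 58.4 ± 23.2 against 270.4 ± 75.2. Of mechanical stimulation genes 11 of 17 were higher (median 1.18, adjusted p = 0.0295, or 0.0586 with the library axis as a covariate). Heat shock genes were higher in 7 cases, or 10 adjusted over the list alone, a call that was lost (adjusted p = 0.341). SLC22A6 was lower by -1.08 ± 0.24, at 372 ± 2.54 against 815 ± 236 (limma adjusted p = 5.29e-04), and the efflux transporter gene ABCC2 was higher by 3.83 ± 0.51.

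Tenofovir against PFOA called 427 genes in the CN OAT1 line (267 higher and 160 lower). The higher share was 62.5%, or 34.5% rescaled (median moved by -0.27) and 41.0% with quantile normalization (-0.16); the directions of the lists named here held under both. The count was 248 without tenofovir replicate 1. Against the single untreated library, which was assumed to vary like the other groups, 421 genes were called (260 higher and 161 lower; 61.8% higher, or 44.2% rescaled with a shift of -0.24 and 43% quantile with -0.22). Of these 239 were called in the same direction against PFOA. With only the groups of each comparison the counts were 259 and 107, and the second was 730 with sample weights. With the library axis as a covariate 151 were called, 111 of them kept from the 421. There 24 of 36 cell cycle genes rose, or 27 adjusted over the list alone (median 1.49, adjusted p = 4.74e-05 with an estimated correlation, 3.29e-06 with the axis). Metallothionein genes were lower than in the single untreated library, with a median of -3.08. On the library axis MT2A and MT1G had loadings of -0.0773 and -0.0518, and MT1E and MT1M had smaller ones (-0.00918 and -0.0103). That library lay at the low end of the axis (-17.5), so part of this fall may come from its place. The p53 genes rose in 6 (median 1.01, adjusted p = 0.0124), and the cholesterol call was lost (0 rose and 5 fell, adjusted p = 0.292).

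**Figure D5:**
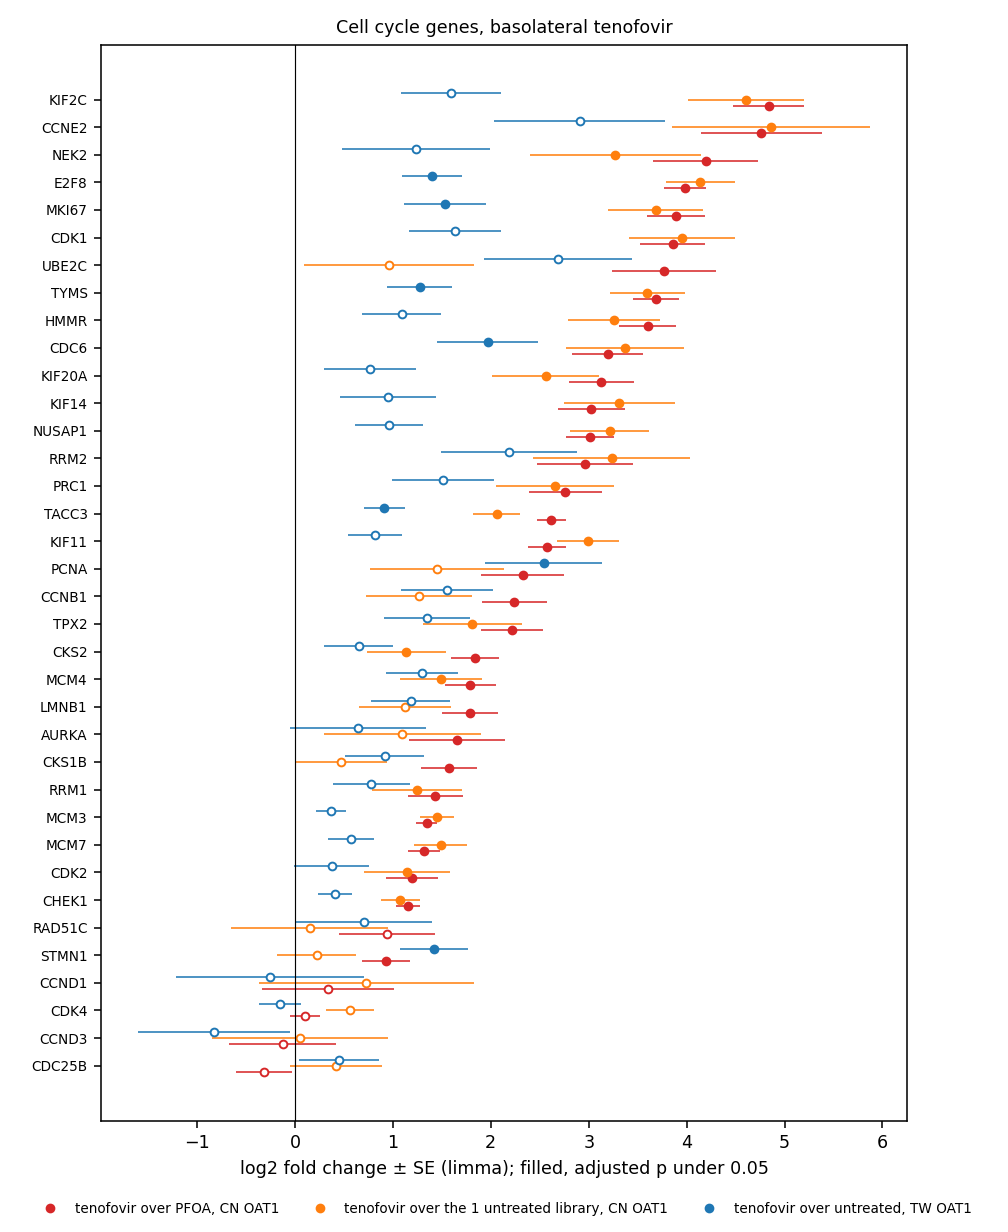
Log2 fold change with its standard error for the 36 tested cell cycle genes after basolateral tenofovir, in CN OAT1 cultures against PFOA (red) and against the 1 untreated library (orange), and in TW OAT1 cultures against untreated (blue); filled points passed an adjusted p of 0.05. The list medians were 2.28, 1.49 and 1.02.

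The difference between tenofovir and PFOA on CN differed between the lines by the test of the interaction, which called 239 genes (175 higher and 64 lower in the OAT1 line; 73.2% higher, or 45.7% rescaled with a shift of -0.28 and 51.9% quantile with -0.17). It called 137 without CN OAT1 tenofovir replicate 1 and 125 with only the groups of the comparison. Cell cycle genes were higher in 28 cases, or 31 adjusted over the list alone (median 1.84, adjusted p = 4.61e-07 with an estimated correlation), p53 genes in 12, or 15 (median 1.55, adjusted p = 4.17e-05), and mechanical genes in 8, or 10 (median 1.36, adjusted p = 0.0206). Metallothionein genes were lower in 5 cases and higher in 1 (median -1.85, adjusted p = 7.54e-04), and calls for cholesterol and heat shock genes were lost (adjusted p = 0.238 and 0.527). Against untreated cultures the same interaction called 335 genes (188 higher and 147 lower; 56.1% higher, or 45.3% rescaled with a shift of -0.22 and 41.2% quantile with -0.22). This count was 167 without CN Parent untreated replicate 3, 216 without CN Parent basolateral tenofovir replicate 3, 215 without CN OAT1 tenofovir replicate 1, 93 with the axis, and 37 with only the groups of the comparison. There cell cycle (19 higher, median 1.44, adjusted p = 0.00263), metallothionein (5 lower, median -2.94, adjusted p = 0.00263) and p53 genes (5 higher, median 0.96, adjusted p = 0.0489) differed, and calls for mechanical and cholesterol genes were lost (adjusted p = 0.208 and 0.277).

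Basolateral tenofovir responses of the OAT1 line shared 17 genes in the same direction between platforms and 1 in opposite directions, against 3.74 for independent lists, while across genes the fold changes correlated at r = 0.0525. Of the 421 genes called on CN 201 (47.7%) had the same sign in the TW OAT1 line. In the TW Parent line basolateral tenofovir called 0 genes (limma, 16 at an unadjusted p under 0.05, edgeR 0 and DESeq2 0). There 321 of the 421 (76.2%) had the same sign, with r = 0.251 across genes. On the library axis the CN OAT1 untreated library lay at -17.5 and the TW Parent untreated libraries at -17.6, 3.20 and 4.84. The TW OAT1 untreated libraries lay at 2.63 and 10.1. Shared signs could therefore not be separated from the place of the untreated libraries on that axis. The platforms' responses differed for 232 genes (146 higher and 86 lower on CN; 62.9% higher, or 33.2% rescaled with a shift of -0.36 and 43.8% quantile with -0.14), but for 11 with the library axis as a covariate. That count was 107 without CN OAT1 tenofovir replicate 1, 16 without TW OAT1 untreated replicate 3, 138 without TW OAT1 basolateral tenofovir replicate 1, 48 without its replicate 2, 59 with the replicate number as a block, 558 with sample weights, and 56 with only the groups of the comparison. Cell cycle genes were higher on CN in 11 cases (median 0.95, adjusted p = 0.218 with an estimated correlation), and the cholesterol call was lost as well (adjusted p = 0.218).

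In the Parent line on CN 10 genes rose with at least 2 compounds, all against the same 2 shallow untreated libraries (396300 and 324548 reads). The count tests called fewer genes for cisplatin, tenofovir and PFOA there: 4, 0 and 0 with edgeR, and 9, 3 and 0 with DESeq2. KRT18, an epithelial keratin, rose by 2.57 ± 0.44 with cisplatin, 2.54 ± 0.44 with tenofovir and 2.35 ± 0.44 with PFOA, and RAD21, a cohesin subunit, by 3.29 ± 0.60, 3.14 ± 0.60 and 3.11 ± 0.60. KRT18 stood at 9.08 in untreated replicate 2, 192 in replicate 3 and 251 ± 45.1 over the treated libraries (SD, n = 18), and both genes lost their calls in each comparison without replicate 2. Tenofovir called 10 genes (9 higher and 1 lower), 32 without untreated replicate 3 6 without basolateral tenofovir replicate 3 and 0 with only the groups of the comparison. PFOA called 8 (8 higher), 46 without untreated replicate 3 and 1 with only the groups of the comparison. Cisplatin and tenofovir shared 8 genes against 0.0943 for independent lists, cisplatin and PFOA 7 against 0.0812, and tenofovir and PFOA 7 against 0.0430. In 20 simulated draws of unchanged groups against these controls 2.65 genes on average, and at most 8, were called with at least 2 compounds, against the 10 observed. Fold changes of the 3 pairs correlated across genes at 0.802, 0.790 and 0.816, with 0.788, 0.791 and 0.788 simulated. Their covariances were 0.286, 0.303 and 0.271, with 0.233, 0.232 and 0.233 simulated. The simulated groups shared the same controls, so correlations of this size could arise from shared controls alone. The count of 10 and the observed covariances lay above the simulated values. The controls, at 2 libraries, could not be split. The simulated genes varied separately, without the library axis, so the simulated counts may be too low. The platforms' responses differed for 8 genes with tenofovir (7 higher and 1 lower on CN; 4 with edgeR, 1 with only the groups of the comparison) and 3 with PFOA (0 with edgeR, quantile normalization or only the groups of the comparison), and across genes the responses on CN and TW correlated at -0.0872 and -0.0799. No gene list was called for tenofovir or PFOA in the CN Parent line.

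PFOA, a persistent fluorinated surfactant, called few genes in the fit over all groups. In the Parent line on TW it called 1, SAT1, which fell by 1.83 ± 0.35 from 36277 ± 7639 (SD, n = 3) to 11845 ± 9126 (SD, n = 6; limma adjusted p = 0.00684). This count was 2 without TW Parent untreated replicate 1, and 0 without untreated replicate 2, untreated replicate 3 or apical PFOA replicate 2. SAT1 was also called lower with cisplatin on TW against the same untreated libraries, so the falls with the compounds are not independent. Calls for cell cycle, cholesterol and hypoxia genes were lost (adjusted p = 0.262 each with an estimated correlation). In the OAT1 line on TW limma called 0 genes (74 at an unadjusted p under 0.05; edgeR 0, DESeq2 0), 1 without apical PFOA replicate 3 and 2 without basolateral replicate 2. Calls for cholesterol and hypoxia genes were lost (adjusted p = 0.259 each), and rescaling moved the median of all genes by 0.17. The interaction of line and PFOA called CYP1B1 alone, a count that 10 single omissions of libraries, edgeR and DESeq2 took to 0. The CYP1B1 call was also lost without TW OAT1 untreated replicate 2, where another gene was called. List calls for cholesterol (adjusted p = 0.0682) and hypoxia genes (0.0788) were lost, and rescaling moved the median of all genes by 0.16. On CN the only untreated OAT1 library lay at -17.5 on the library axis, and the test assumed that it varied like the other groups. From that library the PFOA libraries differed in 8 genes (6 higher and 2 lower, 75.0% higher, or 100% rescaled and 52.4% quantile), among them SLCO1B1 (3.28 ± 0.43). Metallothionein genes were lower in 2 of 7 cases, or 4 adjusted over the list alone (median -0.86, adjusted p = 0.028). A response to PFOA could not be separated from the place of that library. That count was 17 without apical PFOA replicate 1, 2 without apical replicate 2 or basolateral replicate 3, 5 without apical replicate 3 or basolateral replicate 2, 4 without basolateral replicate 1, and 2 with the library axis as a covariate. It also rose, to 63 with DESeq2, 68 with only the groups of the comparison and 348 with sample weights, while edgeR called 9 (2 higher and 7 lower), so no size or direction was settled.

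The side of dosing was tested over all platform and line combinations that held both sides. For tenofovir 35 genes differed (28 higher and 7 lower from the basolateral side). Cell cycle genes were higher in 15 of 36 cases, or 25 adjusted over the list alone (median 0.64, adjusted p = 1.74e-07 with an estimated correlation), with MKI67 higher by 1.17 ± 0.21 (n = 8 basolateral and 9 apical, limma adjusted p = 4.83e-04). Metallothionein genes were lower in 1 of 7, or 4 (median -0.39, adjusted p = 6.65e-04), and the interferon call was lost (adjusted p = 0.151). The count was 23 without TW Parent basolateral tenofovir replicate 3 and 18 without TW OAT1 basolateral tenofovir replicate 2. It was 124 with sample weights and 21 without libraries under 500000 reads. The TW OAT1 cultures alone gave 77 genes by side, and the side was not tested in the Parent line alone. The average may therefore rest mainly on the OAT1 line. For cisplatin limma called 0 genes by side (84 at an unadjusted p under 0.05; edgeR 0, DESeq2 1, 10 with sample weights), with the interferon list upward and 0 members past the threshold (median 0.32, adjusted p = 0.0366 with an estimated correlation, 0.0914 with the library axis as a covariate). Omitting CN Parent apical cisplatin replicate 1, CN Parent basolateral cisplatin replicate 3, TW Parent apical cisplatin replicate 2 or TW Parent basolateral cisplatin replicate 2 gave 1 gene. For PFOA limma called 0 (69 at an unadjusted p under 0.05; edgeR 0, DESeq2 0).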

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

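The tests of read depth, transcript length, the untreated and tenofovir libraries, the compounds, the dependence on the line and the splits of the samples were chosen after results were seen; the test of GC content was written before. No group held 4 to 10 samples, so single samples far from the rest of their group were not tested for.

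In the Parent line the responses to the compounds on CN and TW differed for a few genes by the test of the interaction, as CN minus TW. With cisplatin these were IFITM3 (2.22), KRT18 (2.87), RAD21 (3.56) and SAT1 (2.42), and with PFOA they were ACLY (2.68), KRT18 (2.55) and RAD21 (3.43). With tenofovir they were ACLY (2.50), C2CD5 (-2.83), IFITM3 (2.24), KRT18 (2.82), PRKAB1 (1.6), PRSS23 (2.97), RAD21 (3.44) and SAT1 (2.48). The cisplatin count of 4 became 20 without CN Parent untreated replicate 3, 0 without TW Parent untreated replicate 1 and 2 without TW Parent untreated replicate 2 or replicate 3. It was 7 without CN Parent apical cisplatin replicate 1 or TW Parent apical cisplatin replicate 2, and 2 and 1 without TW Parent basolateral cisplatin replicate 2 and replicate 3. The tenofovir count of 8 became 19 without CN Parent untreated replicate 3 and 2 without TW Parent untreated replicate 1. The PFOA count of 3 became 6 and 22 without CN Parent untreated replicate 2 and replicate 3, and 5 without TW Parent basolateral PFOA replicate 2. It was 0 without any of the 3 TW Parent untreated libraries, CN Parent apical or basolateral PFOA replicate 1 or replicate 3, TW Parent apical PFOA replicate 3 or TW Parent basolateral PFOA replicate 3.

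On TW the lines differed in their responses, as OAT1 minus Parent. With cisplatin BAX (-0.72) and UGT1A10 (-1.28) differed, as did the p53 list (median -0.59) and the cholesterol list (median 0.36). The count of 2 became 0 without any of TW Parent untreated replicate 2, TW Parent apical cisplatin replicate 1 or 2, TW Parent basolateral cisplatin replicate 2, TW OAT1 untreated replicate 2 or 3, TW OAT1 apical cisplatin replicate 1 or 2 or TW OAT1 basolateral cisplatin replicate 2 or 3. It was 1 without TW Parent basolateral cisplatin replicate 3 and 3 without TW Parent untreated replicate 1. With tenofovir FKBP5 (1.55), GDF15 (1.31), HLA-DRA (3.29), IFI6 (1.58), IFIT1 (1.91), NAMPT (3.62), TRIM22 (1.13) and the interferon list (median 1.26) differed. With PFOA CYP1B1 (1.81) differed, and its count of 1 became 0 without any of TW Parent untreated replicate 1 or 2, TW Parent apical or basolateral PFOA replicate 2 or 3, TW OAT1 untreated replicate 3, TW OAT1 apical PFOA replicate 2 or 3 or TW OAT1 basolateral PFOA replicate 2. It was 2 without TW Parent apical PFOA replicate 1. With basolateral tenofovir ASF1B (2.48), CASP1, a bimodal gene in the Parent line (-6.01), COA6 (-5.08) and MT1M (-1.88) differed, with the cell cycle list (median 1.07) and the metallothionein list (median -0.75).

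The platform effect differed between the lines for 144 genes, with list medians of 0.88 for cholesterol, -0.63 for interferon and -0.72 for metallothionein genes. The response to basolateral tenofovir differed between platforms in the OAT1 line for 232 genes. On CN it differed between lines for 335 genes against untreated cultures (medians of 0.96 for p53, 1.44 for cell cycle and -2.94 for metallothionein genes). Against PFOA it differed for 239 genes (medians of 1.55 for p53, 1.84 for cell cycle, 1.36 for mechanical and -1.85 for metallothionein genes).

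The axis of within-group variation took 44.5% of the variance in the Parent line and was not a group of the study, so no biological explanation was tested. Read depth as its whole source was argued against, with r = -0.221 across the 40 Parent libraries after group means were removed (Spearman rho -0.227, two-sided permutation p = 0.172 for r, 100000 permutations, r = -0.277 without the 2 libraries farthest from the median). Loadings followed the length of the longest transcript across genes (rho 0.362, over 1092 of 1099 genes). Length, or a trait of genes that goes with it, may therefore contribute. RNA quality was not measured here. GC content (rho -0.162 across genes) was left open, and genes are not independent replicates. In the TW OAT1 libraries the first component correlated with this axis at 0.568 across genes, and in the CN OAT1 libraries at 0.0783.

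In the CN Parent line 10 genes rose with at least 2 compounds. Among them IFITM3, KRT18, RAD21, RNF19B, RPS27L, TOMM20 and VPS28 were lower in untreated replicate 2 than in replicate 3. That 1 untreated library may be the source of these rises. ACLY and PRSS23 were instead lower in replicate 3, and COL16A1 stood at 0 in both. For these genes replicate 2 was not the lower control. COL16A1 and PRSS23 lay near the counting floor, however, since 1 read stood for 2.27 and 2.75 in these untreated libraries. Over the treated libraries COL16A1 averaged 3.86 ± 2.42 and PRSS23 15.2 ± 7.43 (SD, n = 18), and untreated PRSS23 stood at 6.81 and 0. Low read depth as the source was left open. The 10 genes had a median deviation of 0.276 in the 3 other Parent libraries of low depth, where a loss through depth would lower them. Among those libraries, however, CN basolateral tenofovir replicate 1 and replicate 3 had helped to choose the genes. Each was compared with replicate 2 of its group alone, so the test could not decide. A response to the compounds was left open, since against untreated replicate 3 alone the median rise of the 10 genes was 0.425 with no second control.

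Basolateral tenofovir in the CN OAT1 line called 421 genes against a single untreated library. That library as the whole source was argued against, with 239 of the 421 called in the same direction against the 6 PFOA libraries, and although both comparisons share the 3 tenofovir libraries, only the real one of the 84 splits of the tenofovir and PFOA libraries gave as many (138 the highest other). Its place on the library axis may account for part, since 111 of the 421 were kept with the axis as a covariate, where the median size of the change went from 1.40 (median SE 0.404) to 0.67 (median SE 0.327). The score is taken from the whole expression of a library, so a response in genes of the axis moves it too. The covariate can therefore also remove part of a response. A single tenofovir library was argued against for the cell cycle list, with adjusted p = 2.11e-09 with an estimated correlation without replicate 1. The rise of the cell cycle list against PFOA depended on the line (adjusted p = 4.61e-07 with an estimated correlation), and the transporter cannot be separated here from other differences between the lines.

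Splits of the samples into other groups of the same sizes gave 1 of 100 as large, the real one, for the platform in the Parent line (575 real, 245 the highest other), the platform in the OAT1 line (444, 248) and the line on TW (948, 294) and CN (757, 509). For tenofovir against PFOA on CN 1 of 84 was as large (427, 309). No other split drawn was as large for these, which argues against chance. For the side of tenofovir dosing 2 of 100 were as large (35 real, 37 the highest other). This argues against chance less firmly, since another split called more genes than the real one. Chance was not excluded for cisplatin in the TW Parent line (3 of 56 as large, 4 real, 169 the highest other) or PFOA there (13 of 84, 1 real, 446). For tenofovir there (84 of 84, 0 real, 1), the side of cisplatin (100 of 100, 0 real, 1) and the side of PFOA (100 of 100, 0 real, 8) the splits could not tell, since with a real count of 0 every split is as large. The split with 446 genes set untreated, apical PFOA and basolateral PFOA replicate 1 apart, at -17.6, -12.2 and -15.2 on the library axis, and like the split with 169 genes it points to a structure of the samples. Replicates 2 and 3 of those groups lay between 0.291 and 5.08, so the number did group these samples, and the count for PFOA was 1 with the replicate block too. Basolateral tenofovir in the TW Parent line had a real count of 0 too, and allowed only 10 splits (10 of 10, 0 real, 0 the highest other).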

How the results depend on the processing

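Omission of bimodal genes, omission of libraries under 500000 reads, the library axis as a covariate and averages without the untreated groups were tests chosen after results were seen. Of the 36 counts, those within 1.5 times the reported count numbered 32 with a pseudocount of 0.5 or with rescaled totals, 34 without bimodal genes, 31 with a mean of at least 50 or with a replicate block, and 30 with no filter. They numbered 29 with quantile normalization, 27 with edgeR, 24 with a pseudocount of 10, 22 with the library axis, 19 with DESeq2, 14 with only the groups of a comparison and 14 with sample weights. Without libraries under 500000 reads 25 counts could be computed, and 20 were within that range; those that need the CN Parent untreated libraries could not. Without the untreated groups, which hold the single CN OAT1 untreated library, all 3 averages that include it stayed within that range: 444 became 417, 757 became 824 and 144 became 135. The platform count in the Parent line (575) ranged from 457 to 732 over these settings. Over all groups replicate numbers did not pair samples, although replicate 1 lay apart from the others in the TW Parent untreated and PFOA groups: the median correlation was 0.000279 between libraries of the same number (149 of 739 over 0.1) and -0.00462 between those of different numbers (305 of 1475). Where omission left an arm with 1 library, that library was assumed to vary like the other groups. The fit of the sample weights stopped before its tolerance was reached, and a group of 1 library cannot set its own weight. Depth limits the low genes, most of all in the 6 libraries under 500000 reads. The cause was not tested for any of the following counts, except that only the groups of a comparison leaves fewer samples and a filter changes the genes tested.

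With only the groups of a comparison, counts were 19 for the platform in untreated Parent cultures, 163 for the line in untreated TW cultures, 1, 2 and 2 for cisplatin, tenofovir and PFOA in TW Parent, and 7, 0 and 1 in CN Parent. They were 1 for cisplatin and 1 for PFOA in TW OAT1, 107 for basolateral tenofovir and 68 for PFOA in CN OAT1, and 7 for basolateral tenofovir in TW OAT1. They were 1, 1 and 0 for platform by cisplatin, tenofovir and PFOA, 1 and 0 for line by cisplatin and PFOA on TW, 56 for platform by basolateral tenofovir in OAT1, 259 for tenofovir against PFOA, and 37 and 125 for line by basolateral tenofovir and line by tenofovir against PFOA on CN.

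With sample weights, counts were 85 for the platform in untreated Parent cultures, 66, 6 and 7 for cisplatin, tenofovir and PFOA in TW Parent, and 3, 2 and 3 in CN Parent. They were 8 for cisplatin in TW OAT1, 730 and 348 for basolateral tenofovir and PFOA in CN OAT1, 5 for platform by tenofovir, 6, 19, 2 and 16 for line by cisplatin, tenofovir, PFOA and basolateral tenofovir on TW, and 10 and 124 for the side of cisplatin and tenofovir. They were 219 for platform by line, 52 for basolateral tenofovir and 174 for its side in TW OAT1, 558 for platform by basolateral tenofovir in OAT1 and 2 for basolateral tenofovir in TW Parent.

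DESeq2 gave 7, 3 and 2 for cisplatin, tenofovir and PFOA in TW Parent, 9, 3 and 0 in CN Parent, 9 for cisplatin in TW OAT1, and 63 for PFOA in CN OAT1. It gave 2 and 5 for platform by cisplatin and tenofovir, 4, 14, 0 and 21 for line by cisplatin, tenofovir, PFOA and basolateral tenofovir on TW, 1 for the side of cisplatin, and 49 and 124 for basolateral tenofovir and its side in TW OAT1. edgeR gave 4, 0 and 0 for the compounds in CN Parent, 0, 4 and 0 for platform by cisplatin, tenofovir and PFOA, and 0, 0 and 10 for line by cisplatin, PFOA and basolateral tenofovir on TW.

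A pseudocount of 10 gave 14, 5 and 3 for the compounds in CN Parent, 8, 32 and 2 for those in TW OAT1, 5 and 0 for platform by tenofovir and PFOA, 15, 0 and 20 for line by tenofovir, PFOA and basolateral tenofovir on TW, and 56 for basolateral tenofovir in TW OAT1. A pseudocount of 0.5 gave 3 for cisplatin in TW OAT1, 13 for PFOA in CN OAT1, and 9 and 8 for platform by cisplatin and PFOA. No filter gave 23 and 15 for tenofovir and PFOA in CN Parent, 4 for PFOA in CN OAT1, 5 for platform by PFOA, and 0 and 0 for line by cisplatin and PFOA. A mean of at least 50 gave 5 and 4 for tenofovir and PFOA in CN Parent, 3 for cisplatin in TW OAT1, 5 for platform by PFOA and 17 for the side of tenofovir.

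Quantile normalization gave 6 and 5 for tenofovir and PFOA in CN Parent, 21 for PFOA in CN OAT1, 0 and 0 for platform by cisplatin and PFOA, and 1 and 9 for line by cisplatin and basolateral tenofovir on TW. Rescaled totals gave 4 for PFOA in CN OAT1, 0 for platform by PFOA, and 0 and 9 for line by cisplatin and basolateral tenofovir on TW. The replicate block gave 13 for tenofovir in TW OAT1, 2 for PFOA in CN OAT1, 7 and 6 for platform by cisplatin and PFOA, and 59 for platform by basolateral tenofovir in OAT1. Without bimodal genes the counts were 13 for PFOA in CN OAT1 and 7 for platform by cisplatin.

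The library axis as a covariate gave 20 and 25 for tenofovir and PFOA in CN Parent, 11 and 34 for cisplatin and tenofovir in TW OAT1, 151 and 2 for basolateral tenofovir and PFOA in CN OAT1, and 11 for platform by PFOA. It gave 13 for line by basolateral tenofovir on TW and 93 on CN, 1 for the side of cisplatin, 251 for platform by line, 61 and 130 for basolateral tenofovir and its side in TW OAT1, and 11 for platform by basolateral tenofovir in OAT1. Without libraries under 500000 reads the counts were 3 for cisplatin in TW OAT1, 1 and 0 for line by cisplatin and PFOA on TW, 21 for the side of tenofovir and 122 for line by tenofovir against PFOA on CN. Of the 78 called list tests 38 held with an estimated correlation.

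Omitting each library in turn gave 63 to 126 for the platform in untreated Parent cultures, 520 to 612 for its average in Parent and 386 to 467 in OAT1, 182 to 345 for the line in untreated TW cultures, and 902 to 977 on TW and 723 to 757 on CN for its average. Ranges for cisplatin, tenofovir and PFOA were 3 to 6, 0 to 0 and 0 to 2 in TW Parent, 8 to 35, 6 to 32 and 7 to 46 in CN Parent, and 0 to 12, 7 to 20 and 0 to 2 in TW OAT1. In CN OAT1 they were 297 to 474 for basolateral tenofovir, 2 to 17 for PFOA and 248 to 478 for tenofovir against PFOA. In TW OAT1 they were 13 to 36 for apical and 3 to 19 for basolateral tenofovir and 18 to 78 for its side, and 0 to 0 for basolateral tenofovir in TW Parent. Platform by cisplatin, tenofovir and PFOA ranged over 0 to 20, 2 to 19 and 0 to 22. Ranges were, for line by cisplatin, tenofovir, PFOA and basolateral tenofovir on TW, 0 to 3, 1 to 8, 0 to 2 and 2 to 6, and for the sides of cisplatin, tenofovir and PFOA 0 to 1, 18 to 41 and 0 to 0. Platform by line ranged over 128 to 173, platform by basolateral tenofovir in OAT1 over 16 to 288, line by basolateral tenofovir on CN over 167 to 402 and line by tenofovir against PFOA over 137 to 273. RNF19B with tenofovir in CN Parent reversed to -0.0834 without CN Parent untreated replicate 2 and was 3.38 without replicate 3.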

Other observations

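The tests of apical tenofovir in the TW OAT1 line were chosen after results were seen. PSMB9 and ISG20, an antiviral exonuclease, were higher in the OAT1 line on CN, by 1.56 and 3.72, while the interferon-induced gene IFI44L was lower there, at -3.31 ± 0.27. In the TW OAT1 line apical tenofovir also raised NAMPT, which makes NAD (3.68 ± 0.67), and CXCL1, a neutrophil chemokine (1.40 ± 0.30), the latter a call lost without TW OAT1 untreated replicate 2.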
